A study of Gallus gallus with 4 samples.

How the data were processed

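Cultured chicken embryo fibroblasts were passaged when confluent until passage 18, and total RNA from passage 4 and passage 18 was labelled with 2 µg of input and hybridised to 2-colour arrays, per the labels' protocols. The labels give passage 4 in Cy3 and passage 18 in Cy5 on all 4 arrays. The deposited series table holds 1 log2 ratio per spot and array, with 4 decimals. A second deposited table holds the linear ratio of the same spots, with column names that end in the extension of GenePix result files, per the file headers. The log2 of that linear ratio differed from the log2 table by at most 5.00e-05. The authors' columns for the mean and SD, which the header calls log fold changes, equal the arithmetic mean and SD of the 4 linear ratios and were not used for any result. Scanner settings, background correction and normalization are not given in the sources used here, nor is the channel that forms the numerator. The log base was settled from both tables, while centring and direction stay open. All columns of values per sample were matched to a sample through its accession or description. No array correlated below 0 with another, so no sign was turned.

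The table has 45220 numbered spots, and 1 row without a spot number was left out. Control and empty spots (3186) were kept out of all tests. Signals per channel were not used here, so the filter on dim probes could not be run, signal over background is unknown, and only the number of arrays describes the precision. Of the gene probes, 66 carry a RefSeq transcript accession, and 51 of these matched the RefSeq gene table of the chicken assembly GRCg7b after removal of versions, which gave 50 genes. HSPA2 had 2 probes. A further 244 probes carry a microRNA name in the file itself, 118 names in all, of which the names of 184 probes are also listed in the RefSeq table. No probe had several names and 41739 had none. Of these, 3803 carry no accession at all, and accessions other than RefSeq were not looked up. Probes of a name were averaged on the log2 scale. That microRNA names count as named features was decided after the files had been seen. The named table thus had 168 features.

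The log2 ratio of each feature over the 4 arrays was tested against 0 with lmFit and eBayes of limma 3.58.1 in R 4.3.3, without covariates, and p-values were adjusted by Benjamini-Hochberg over all features of the table. Calls had an adjusted p under 0.05, and a 2-fold call also an absolute log2 ratio of at least 1. Every adjusted p of a gene, microRNA name or probe comes from this limma model. Each call for a gene is from the named table, and the 42034 gene probes were tested in a table of their own. The p-values of both tables treat the arrays as independent. The named table had a prior variance of 0.0378 with 4.93 prior degrees of freedom, against 0.110 and 5.76 for all gene probes.

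Before the data were examined, the comparison, the alternatives, 24 gene lists and the rule for named genes were fixed. The rule takes the 7 highest and the 7 lowest called genes with the same sign on all 4 arrays, 16 genes in any case, and called members of the lists. Only 6 higher genes qualified. TGFB2, the one member of a list among the named genes, was not called and so lies outside the rule. It was added after the values were seen and is counted among the 14 named results. Other genes outside the rule are marked in the text as chosen after their values were seen. Lists of 3 or more measured members were to be tested with camera. The 9 microRNA lists were tested with camera at a preset correlation of 0.01 and with an estimated one, adjusted over the 9 lists. They were also tested with fry, which compares each list with 0 and not with the other names, adjusted in the same way.

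The alternatives fixed beforehand left out each array, centred each array on its gene probe median, quantile-normalized the ratios between arrays, used the linear table, took the probe with the median ratio, set trend and robust in eBayes, tested all probes, and used treat against a 1.5-fold change. For a name with 2 probes, the probe taken as the median was always the lower one. After the data had been seen, 3 alternatives were added: centring on the dark corner and negative control spots, averaging arrays 1 and 3 and arrays 2 and 4, and a variance prior from all gene probes. The limma test was tested on simulated data for 42034 probes with 200 changed. With independent arrays it recovered 1.61% of changes of 0.5 log2 units, 29.2% of changes of 1 and 100% of changes of 2, with 3 false calls. With noise shared within pairs of arrays at a correlation of 0.601, the shares were 3.13%, 63.4% and 98.5%, and the false calls rose to 64. For the 168 named features with 40 changed and independent arrays, it recovered 85.7% of changes of 0.5 and 100% of changes of 1 and 2, with 3 false calls. Noise shared within pairs was not simulated for these features. No simulation had an offset of whole arrays or as many changes as were called in the data, so these rates may not hold for the data.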

Results

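Chicken embryo fibroblasts are primary connective tissue cells that stop dividing after prolonged culture, a state called senescence. Cells at passage 4, which the labels call healthy, were compared with cells at passage 18, which they call senescent, to find transcripts whose abundance differed between the passages. RNA of both passages was hybridised together on 2-colour oligonucleotide arrays, and 4 arrays formed 1 group. Each array gave a ratio for 45220 spots, of which 42034 were gene probes and 3186 were control or empty spots. Names could be given to 295 gene probes (0.702%), which covered 50 genes with a RefSeq accession and 118 microRNA names, and the remaining 41739 probes were counted without a name. The labels call all 4 arrays biological replicates, whereas the design text gives 1 sample per passage, so the p-values measure only the spread between arrays, which may be technical. Signals of the separate channels were not used here, and the number of arrays limits the precision.

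Values are log2 ratios of passage 18 over passage 4, a direction that is likely but not settled. The labels place passage 4 in Cy3 and passage 18 in Cy5 on every array and call passage 18 the experimental sample, and Cy5 over Cy3 is the customary ratio, but no source used here names the numerator. With passage 4 as the numerator, higher and lower would exchange throughout. Dye and passage were not separated by a dye swap in the labels.

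The transcripts of 3 genes were at least 2-fold lower at passage 18. SOCS2, a feedback inhibitor of cytokine and growth hormone signalling, had a log2 ratio of -2.07 ± 0.44 (SD, n = 4), which is 0.238 times the passage 4 level, with an adjusted p of 9.03e-05 (limma, Benjamini-Hochberg). TENM2, a teneurin that mediates adhesion between cells, stood at -2.04 ± 0.50 (adjusted p = 0.000145), or 0.244 times that level. LPIN2, a phosphatidate phosphatase of glycerolipid synthesis, stood at -1.16 ± 0.13 (adjusted p = 9.03e-05), or 0.448 times. The beta-tubulin gene TUBB6 fell less, with a log2 ratio of -0.82 ± 0.35 and an adjusted p of 0.00151. All 4 genes were below 0 on each of the 4 arrays and passed the threshold under each of the 12 alternative settings of the named table. The linear table holds the same ratios and each of these genes had 1 probe. The settings with the linear table and with the median probe thus could not change their log2 ratios. Trend and robust, averaged pairs of arrays and the prior from all gene probes also left these ratios as they were and changed only the p-values.

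**Figure D1:**
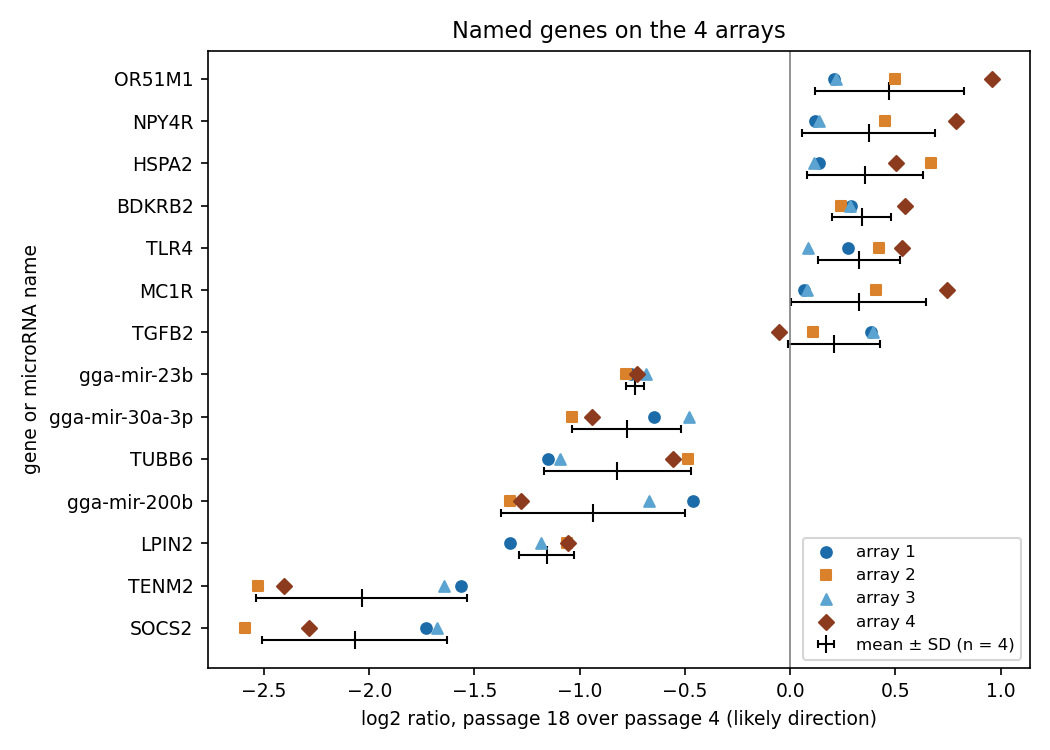
Log2 ratio of passage 18 over passage 4 (horizontal axis, likely direction) for the 14 named genes and microRNA names (vertical axis). Each marker is 1 of the 4 arrays, and the black bars give the mean ± SD. SOCS2 and TENM2 lie near -2 on average, with arrays 2 and 4 below arrays 1 and 3, and the higher genes lie between 0 and 1.

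Of the 50 genes with a RefSeq accession, 17 passed an adjusted p of 0.05, with 10 lower and 7 higher at passage 18. Adjusted over the list alone, 13 passed, 10 of them lower and 3 higher. The higher ones were BDKRB2, OR51M1 and TLR4, while HSPA2, NPY4R, OR52R1 and MC1R did not pass. Besides the 4 genes above, the lower genes were NRF1 at -0.60, EXOSC10 at -0.53, CHRM4 at -0.46, CHRNG at -0.41, PDCD2 at -0.35 and GJA4 at -0.30, all named after their values were seen. NRF1 is a transcription factor for nuclear genes of mitochondrial respiration, EXOSC10 is an exonuclease of the RNA exosome, and CHRM4 and CHRNG encode a muscarinic and a nicotinic acetylcholine receptor chain. Of the 10 lower genes, 7 kept their call under each of the 12 alternatives, and PDCD2, CHRNG and GJA4 lost it under at least 1. GJA4 was no longer called without array 1, at a log2 ratio of -0.26 (adjusted p = 0.0540). Of the 168 features that share the variance prior, 118 are microRNA names, and with a prior from all gene probes 8 genes passed, 1 higher and 7 lower. With the arrays that correlated in pairs averaged, 9 genes passed, 1 higher and 8 lower. In that setting the adjusted p of the named results followed the order of their absolute log2 ratios, whatever their spread over the arrays. The spread of a gene between the pairs thus did not visibly enter its p-value, and this setting did not test it.

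The 7 higher genes differed by small amounts. OR51M1, an olfactory receptor, was the highest, at 0.47 ± 0.35 (adjusted p = 0.0121). NPY4R, a receptor for pancreatic polypeptide, stood at 0.37 ± 0.32 (adjusted p = 0.0252), and HSPA2, a chaperone of the heat shock protein family, at 0.36 ± 0.28 (adjusted p = 0.0219). The 2 probes of HSPA2 disagreed, at 0.18 and 0.53, and with 1 probe taken for each name, here the lower, HSPA2 was not called (adjusted p = 0.238). BDKRB2, the bradykinin receptor, stood at 0.34 ± 0.14 (adjusted p = 0.00826), TLR4, the receptor for bacterial lipopolysaccharide, at 0.33 ± 0.19 (adjusted p = 0.0150), and the melanocortin receptor gene MC1R at 0.33 ± 0.32 (adjusted p = 0.0416). OR52R1, a second olfactory receptor gene named after its value was seen, was called at 0.35 ± 0.36 (adjusted p = 0.0416) although array 1 gave -0.17. OR51M1 was the only higher gene whose call was kept under all 12 alternatives, although its log2 ratio was 0.31 without array 4 (adjusted p = 0.0298). The 1769 spots without a name had medians of 0.16, 0.57, 0.42 and 0.77 on arrays 1 to 4, with a mean of 0.48. None of the 7 higher genes had a mean above that, and no alternative was centred on those spots. NPY4R, HSPA2, TLR4, MC1R and OR52R1 lost their calls without array 2 (log2 ratios of 0.25 to 0.35, adjusted p of 0.0617 to 0.156) and without array 4 (0.19 to 0.31, 0.0531 to 0.154), and OR52R1 also without array 3 (0.33, 0.122). The median of 18 G protein-coupled receptor genes, grouped after their values were seen, was -0.22, 0.27, 0.11 and 0.59 on arrays 1 to 4, beside -0.24, 0.18, 0.11 and 0.48 for the background spots. With each array centred on its background spots, MC1R stood at 0.19 ± 0.15 (adjusted p = 0.262) and NPY4R at 0.24 ± 0.15 (adjusted p = 0.161). BDKRB2 stood at 0.21 ± 0.22 (adjusted p = 0.227) and TLR4 at 0.20 ± 0.24 (adjusted p = 0.256). Of the higher genes, only OR51M1 stayed called, at 0.34 ± 0.17 (adjusted p = 0.0433). There limma used 1 common variance of 0.102 for all named features, so the SD of a gene did not enter its p-value. In that setting 13 genes with a RefSeq accession passed, 1 higher and 12 lower, and with each array centred on the median of its gene probes, 20 passed, 12 higher and 8 lower.

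Gene lists for cell division, secreted factors, matrix and other programmes had been fixed before the data were examined. Only 1 of the 24 lists had a member among the named genes and none had 3, so no shift of these lists could be tested. Accessions other than RefSeq were not looked up, so members of the lists may be among the 41739 probes without a name. That member was TGFB2, a ligand of the transforming growth factor beta family that senescent cells can secrete, and it is named outside the rule, after its value was seen. TGFB2 stood at 0.21 ± 0.22 and did not pass the test (adjusted p = 0.0946), but passed without array 4, at 0.29 (adjusted p = 0.0337). It stood at 0.15 without array 1 and without array 3 (adjusted p of 0.277 and 0.302). With each array centred on its background spots it stood at 0.08 (adjusted p = 0.689). Also not called were the cell cycle kinase gene CDK6, at -0.09 ± 0.17 (adjusted p = 0.369), and the AP-1 component gene JUN, at 0.11 ± 0.09 (adjusted p = 0.261), both named after their values were seen. None of the 16 genes that were to be named in any case, among them cell cycle inhibitors, was among the named probes, and they were not analysed here.

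Probes that the file names after microRNAs, short RNAs that repress messenger RNAs, gave ratios below 1 almost throughout. Whether these probes measure the short RNAs themselves was not tested. Of 118 microRNA names, 114 passed as lower, none passed as higher and 4 did not pass, with a median log2 ratio of -0.44 and a range of -0.94 to -0.18. Adjusted over the list alone, 115 passed as lower. The lowest were gga-mir-200b, best known from epithelial cells, at -0.94 ± 0.44 (adjusted p = 0.00170), gga-mir-30a-3p at -0.78 ± 0.26 (adjusted p = 0.000949) and gga-mir-23b at -0.74 ± 0.04 (adjusted p = 0.000564), whose 2 probes stood at -0.41 and -1.07. Tested on their own among all gene probes, only the probe at -1.07 passed for gga-mir-23b. Both probes passed for gga-mir-200b and for gga-mir-30a-3p. On arrays 1 and 3 gga-mir-200b stood at -0.46 and -0.67, against -1.33 and -1.28 on arrays 2 and 4. For gga-mir-30a-3p these values were -0.65 and -0.48, against -1.04 and -0.94. Across the 118 names, Pearson r between arrays was 0.02 to 0.72, against 0.70 to 0.88 across genes with a RefSeq accession. The order of the names thus repeated poorly between some arrays. The shift was below 0 under every scaling, with a median of -0.36 after centring on the gene probes and -0.57 after centring on the background spots. With the variance prior from all gene probes, 84 names passed. In the table of all gene probes, which has that prior and an adjustment over 42034 probes, 99 of 244 microRNA probes passed as lower, and 243 had a negative mean. Of the 114 names with 2 probes, both probes passed there for 19 names, 1 probe for 55 and neither for 40. The ratios of 2 probes for a microRNA name had a Pearson r of 0.03 across names (95% interval -0.15 to 0.21), against 0.72 (0.65 to 0.77) across 251 other accessions with 2 probes. The median absolute difference between the 2 probes was 0.19 for microRNA names and 0.23 for the other accessions. In log2 units the probes of a microRNA name thus lay no further apart.

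**Figure D2:**
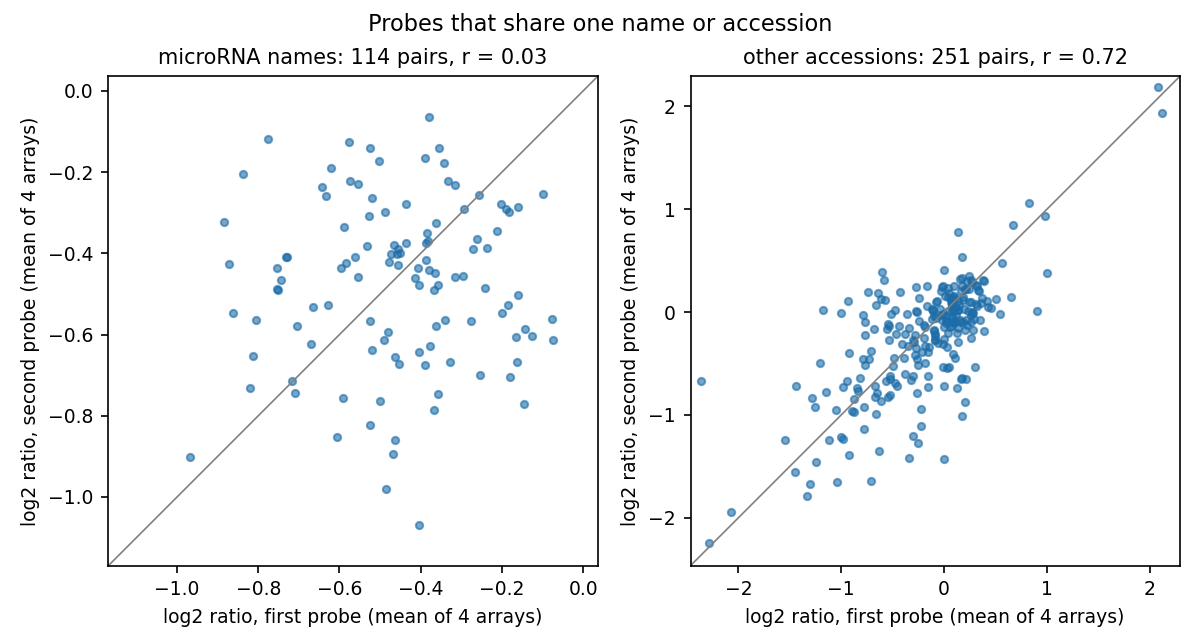
Mean log2 ratio over 4 arrays of the first probe (horizontal axis) against that of the second probe (vertical axis) for the same name or accession, with the line of equal values. The 114 microRNA names in the left panel lie below 0 with r = 0.03, and the 251 other accessions in the right panel follow the line with r = 0.72.

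The microRNA names were grouped into 9 lists written after their overall median, but no single value, had been seen. All measured members passed as lower for the let-7 family (9 of 9, median -0.42), the miR-17-92 and related clusters (12 of 12, -0.39), microRNAs linked to senescence or p53 (13 of 13, -0.46), neural microRNAs (10 of 10, -0.40) and mesenchymal microRNAs (9 of 9, -0.42). In the senescence list, gga-mir-146a stood lowest at -0.73, and in the let-7 family, gga-let-7i at -0.59, both picked as the lowest after their values were seen. Of the muscle microRNAs 6 of 7 passed as lower (median -0.43), of the epithelial 8 of 9 (-0.44), of the blood cell 3 of 4 (-0.57) and of the embryonic stem cell microRNAs 4 of 5 (-0.28). In each of these 4 lists the remaining member did not pass, and these were gga-mir-1b at -0.18, gga-mir-205b at -0.22, gga-mir-155 at -0.25 and gga-mir-302b at -0.20, named after their values were seen. Against the other microRNA names, camera called only the embryonic stem cell list, whose members were less low than the rest (adjusted p = 0.00823), with an adjusted p = 0.659 with an estimated correlation. The other 8 lists had adjusted p of 0.649 to 0.942 with the preset correlation and 0.768 to 0.946 with the estimated one. Against 0, fry gave adjusted p of 0.000359 to 0.0137 for the 9 lists. Almost all microRNA names lay below 0, so the fry result does not set one list apart from another.

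Among all gene probes, 8673 of 42034 (20.6%) passed an adjusted p of 0.05 in limma, 7846 lower and 827 higher at passage 18. At least 2-fold differences were called for 3043 probes, 2799 lower and 244 higher. The lowest probe, A_87_P012980, had a log2 ratio of -6.49 ± 0.64, followed by A_87_P025060 at -5.05 ± 0.37. The highest, A_87_P021100, stood at 6.18 ± 0.45, followed by A_87_P020909 at 4.89 ± 0.71. The ratio had the same sign on all 4 arrays for 15603 probes (37.1%). Independent arrays centred on 0 would share a sign for 12.5% by chance, but these arrays correlated in pairs and were offset from 0, so the share without any change is not known. Lower calls made up the larger part under every scaling, but the split moved to 4224 higher and 9392 lower with each array centred on its gene probe median. Without array 3 the count was 4738. All of these counts treat the arrays as independent. In simulated data with noise shared within pairs, and with fewer changes than were called here, the share of false calls was above 0.05.

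The 4 arrays fell into pairs. Across gene probes, which are not independent replicates, Pearson r was 0.865 between arrays 1 and 3 and 0.852 between arrays 2 and 4, and 0.613 to 0.669 for the other 4 pairs. SOCS2 and TENM2 were lower on arrays 2 and 4 (-2.59 and -2.28 for SOCS2) than on arrays 1 and 3 (-1.73 and -1.68), while TUBB6 was lower on arrays 1 and 3 (-1.15 and -1.09) than on arrays 2 and 4 (-0.48 and -0.56). With both pairs averaged and fitted as 2 samples, 5012 probes passed, 4625 lower and 387 higher, and all 3043 probes called at least 2-fold were called again. Averaging left each mean log2 ratio unchanged, so the 2-fold part of the call could not fail. In that setting 3116 probes were called at least 2-fold. The median log2 ratio of the gene probes was -0.39, 0.0024, -0.14 and 0.22 on arrays 1 to 4, and that of the 757 dark corner and negative control spots was -0.24, 0.18, 0.11 and 0.48. Centring each array on those spots moved the median of all gene probes by -0.13.

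**Figure D3:**
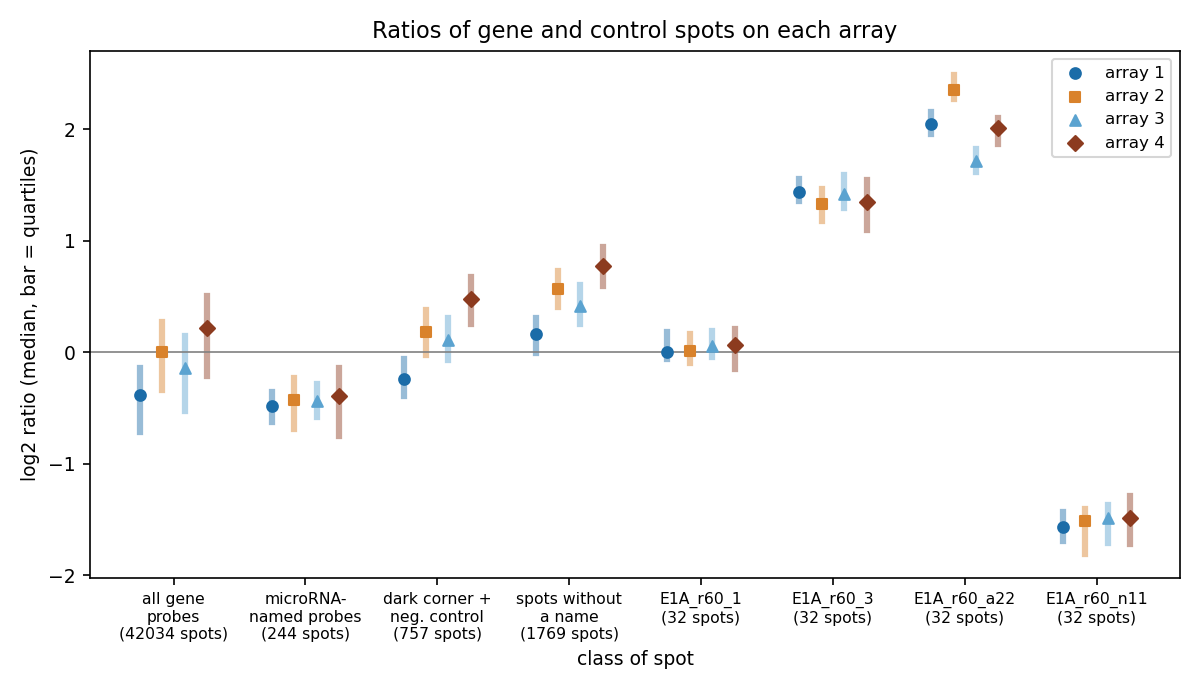
Median log2 ratio (vertical axis, bars from the lower to the upper quartile) of classes of gene and control spots (horizontal axis) on each of the 4 arrays. Gene probes and background spots shift together from array to array, microRNA-named probes stay between -0.48 and -0.39, and the E1A control transcripts keep their sign where they lie away from 0.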

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

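All tests that weigh an explanation in this part were chosen after the pattern had been seen, except the comparison of 2 probes per microRNA name and the turned signs. Of 43 values checked for an array far from the others, 2 stood apart, where chance gives about 1 in 20. BDKRB2 was 0.55 on array 4 and 0.24 to 0.29 on the other arrays. The median of the mesenchymal microRNAs was -0.48 on array 1, against -0.44 on each of the other arrays.

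Control spots outside the comparison also gave ratios away from those of the negative controls. Means over the arrays of the median log2 ratio were 2.03 for E1A_r60_a22, 1.38 for E1A_r60_3, 1.33 for E1A_r60_a104 and 1.28 for E1A_r60_a97. They were -1.58 for E1A_r60_n9, -1.53 for E1A_r60_a135, -1.51 for E1A_r60_n11 and -1.30 for E1A_r60_a107. The 1769 spots without a name had a mean of 0.48, above the negative controls on all 4 arrays.

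Arrays 1 and 3 and arrays 2 and 4 correlated in pairs, with r of 0.865 and 0.852 across gene probes. Ratios of a pair turned by a dye swap are argued against for controls added by dye, since 8 of the 8 E1A transcripts away from 0 kept their sign on all arrays, but a swap in which the controls followed the cell RNA was not tested. Different cell RNA in the pairs stays open: the repeatable SD between pairs was 0.388 for gene probes and 0.149 for E1A transcripts, a ratio of 2.61. The E1A differences between pairs also repeated, with r = 0.96 over 10 transcripts, so a difference in labelling or hybridisation stays open too.

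The negative ratio of the microRNA names is not wholly an offset shared with the gene probes of an array, since with arrays centred on those probes their median was -0.36 and 78 names were still called lower. The difference from the gene probe median was below 0 on all 4 arrays but uneven, from -0.64 on array 4 to -0.10 on array 1 (SD 0.23). A signal that is not specific to the named microRNA may contribute, since the r between 2 probes of a name was 0.0306, in a test that would have argued against it above 0.6. The SD between single microRNA probes was 0.205, against 0.522 for gene probes and 0.156 for background spots, and a narrow range leaves little for 2 probes to share. The 2 probes of a microRNA name differed by a median of 0.19, against 0.23 for other accessions, so the low r cannot decide the question. A lower level of many microRNAs at passage 18 stays open and was not tested on its own, and neither was a dye effect, which the design does not separate from passage. Whether these probes measure the short microRNAs or other RNA was not tested either.

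Turning the signs of the arrays gives 8 patterns, too few for a share under 0.05. In each of the 4 counts, 1 pattern, the real one, gave as many calls. The real counts and the highest among the other patterns were 131 and 2 for named features, 3 and 2 for named features at least 2-fold, 8673 and 0 for gene probes, and 3043 and 0 for gene probes at least 2-fold. All arrays correlated positively with each other, at 0.613 to 0.865 across gene probes. Turned patterns would give low counts whatever the source of the shared ratios, so no conclusion is drawn from these counts.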

How the results depend on the processing

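Background-spot centring, averaging of paired arrays and the prior from all gene probes were chosen after seeing the data. For the 14 named genes and microRNA names, with TGFB2 added outside the rule, 138 of 168 alternative values kept the direction and the side of the threshold, 29 lost the call, 1 gained it (TGFB2 without array 4) and 0 reversed. The calls lost were those of NPY4R, HSPA2, BDKRB2, TLR4 and MC1R, while the 7 lowest and OR51M1 kept theirs. The linear table could not change a value beyond rounding, and the median probe setting could not change that of a gene with 1 probe. For a name with 2 probes that setting took the lower one, so it could only make the log2 ratio of a microRNA name lower. Trend and robust, averaged pairs and the prior from all gene probes left every log2 ratio unchanged, so no direction could reverse there. The 131 named features (7 higher) became 113 to 125 with an array left out, 91 (1 higher) with paired arrays averaged, 92 (1 higher) with the prior from all gene probes and 98 (12 higher) with gene probe median centring. The 3 at least 2-fold became 3 to 4 with an array left out. Tested as all probes, these counts were 8673 and 3043. The count of microRNA names called was 98 to 111 with an array left out and 78 to 117 under all alternatives, none higher. The 17 genes with a RefSeq accession became 14 to 24 with an array left out, 9 with paired arrays averaged and 8 with the prior from all gene probes. Their share of higher calls, 41.2%, was 62.5% without array 1, 21.4% without array 2 or array 4 and 8.33% with trend and robust. The 8673 gene probes became 4738 to 9557 with an array left out, the lowest without array 3, 13616 with gene probe median centring, 13091 with quantile normalization, 15166 with background centring and 5012 with paired arrays averaged. The share of higher calls was 9.54% as reported and 31.0% with median centring. The 3043 probes at least 2-fold became 2518 to 3824 with an array left out and 1465 with treat, which tests against a larger change. Settings that left out or averaged arrays tested fewer samples, and for the others the cause was not tested. With background centring, limma took 1 common variance of 0.102 for all 168 named features, against a prior variance of 0.0378 as reported. With paired arrays averaged and with the median probe, the adjusted p of the named results also followed the order of their absolute log2 ratios. The spread of a feature thus did not visibly enter its p-value there. The filter on dim probes was not run, and neither were the alternatives for the fixed gene lists, which had too few members among the named genes. Signal over background is unknown, so what it limits cannot be told from ratios alone. No paired analysis was possible because there is 1 group and each array already holds both passages.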

Other observations

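Values of 3 receptor families were chosen after they had been seen, and no further test was run on them. Among the melanocortin receptors, MC1R was called higher, while MC2R stood at 0.35 ± 0.58 (adjusted p = 0.130), MC4R at 0.18 ± 0.59 (0.424) and MC5R at -0.04 ± 0.31 (0.762), with no limma call. Among the neuropeptide Y receptors, NPY4R was called higher, and NPY5R at 0.26 ± 0.42, NPY1R at 0.19 ± 0.54 and NPY2R at 0.17 ± 0.34 were not called (adjusted p of 0.142, 0.355 and 0.244 in limma). CHRND, which encodes another chain of the nicotinic acetylcholine receptor, stood at 0.27 ± 0.49 without a call (adjusted p = 0.169), where CHRNG was called lower at -0.41 ± 0.28 (adjusted p = 0.0121). These values are not centred on the background spots, whose median was -0.24 to 0.48 over the arrays, with a mean of 0.13, beside a median of 0.18 for 18 receptor genes. Whether members of a family differ from each other was not tested.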
